A study of Mus musculus with 9 samples.

How the data were processed

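RNA from mouse inguinal adipose stromal cells taken through white adipocyte differentiation was sequenced after culture with sodium alginate, a polysaccharide salt from brown algae, at 0, 50 or 100 µM. Each dose had 3 libraries, 9 in all. Doses were taken from the treatment labels and library names. The titles of the 100 µM libraries say 50 µM, whereas their treatment label and library name say 100 µM, and the latter was used. Titles give day 6 and the protocol gives collection on day 7. The treatment protocol lists insulin (1 µg/ml), dexamethasone (1 µM), IBMX (0.5 mM) and rosiglitazone (1 µM) in the medium at every dose, 0 µM included. The design text does not list rosiglitazone. Nothing in the labels says that the 3 libraries of a dose came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

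The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to the depth of the library) for 41761 genes, per the file headers. Of these genes, 20461 were annotated as protein-coding, 665 had no symbol and 16475 were at 0 in every library. The aligner, the counting tool and their settings are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10, whereas the gene identifiers and scaffold names in the table are those of the C57BL/6NJ strain assembly. Coordinates below are the table's own, on that strain assembly, and were not converted. Each FPKM value multiplied by gene length was a whole multiple of 1 number per library, within a tolerance of 0.01 read, for 100% of values. Whole reads and the scaling total of each library could therefore be rebuilt. Rebuilt reads ranged from 14019672 to 17094467 per library. The scaling total equalled a median-of-ratios size factor times the geometric mean of the read totals, so the deposited values already carried a factor per library. Scaling total over reads averaged 1.02 at 0 µM, 1.02 at 50 µM and 0.973 at 100 µM. The labels do not say whether counting used strand, so reads of overlapping or antisense genes may be mixed, and genes with close copies, such as Ces1d, are uncertain.

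Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, so a fold change is on that scale and understates changes of genes with low values. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 12635 in all. A model with 1 mean per dose was fitted to all 9 libraries, with moderated variances that follow a trend on expression. It gave 3 two-sided comparisons between doses and an F test over the doses, and a slope on dose was fitted separately. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Before the data were examined, 29 gene lists with 732 genes were fixed, of which 690 genes were found by symbol. They cover PPAR signalling, adipogenic transcription factors, mature adipocyte markers, lipid and mitochondrial metabolism, cholesterol synthesis, insulin signalling, glycolysis and hypoxia, progenitor markers, extracellular matrix, Wnt and TGF-beta response, inflammation, interferon, cell cycle, stress responses and markers of other cell types. The 23 lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, and again with the correlation estimated from the data. The fry test, also in limma, was an alternative. It asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The adjusted p of a list is over these 23 lists. Some genes are in several lists, such as Plin1 in PPAR signalling, adipocyte markers, triglyceride synthesis and lipolysis, so list results are not independent. The named genes also followed a rule fixed beforehand. It took, per comparison, protein-coding genes past the threshold with at least 5 FPKM in the higher group and no overlap between the 3 and 3 values, namely the 10 largest increases and 10 largest decreases. For 3 against 3 libraries, chance gives no overlap in 10% of genes. The rule added up to 4 members of each list with the smallest p and 13 genes always reported. Where 5 or fewer members of a list passed, those outside the rule are named too, and these, with genes named beside other small counts or in the closing part, were chosen after their values were seen. A few genes that met these rules are not described here.

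The procedure was tested on simulated reads for the 12635 genes, in 10 draws per comparison. Each draw changed 200 genes and slightly raised the fatty acid synthesis genes. This setting was the same in each comparison, with far fewer changed genes than were called at 100 µM. Genes were drawn independently, so the recovered shares do not give the sensitivity of each real comparison. For 100 µM against 0 µM, 98.9% of genes at 10 FPKM or more that were changed 2-fold were recovered, and 67.0% of those under 10 FPKM. For 50 µM against 0 µM these shares were 98.4% and 67.4%, and for 100 µM against 50 µM they were 98.8% and 66.3%. Changes of 1.5-fold were recovered in 59.4% of genes for 50 µM against 0 µM, 60.4% for 100 µM against 0 µM and 60.3% for 100 µM against 50 µM. Changes of 1.25-fold were recovered in 17.8%, 17.5% and 16.6% of genes in these comparisons, and in 6.89%, 7.55% and 4.51% of genes under 10 FPKM. Among calls in the simulations, 4.73%, 5.49% and 4.87% were unchanged genes, in the order of the comparisons 50 against 0, 100 against 0 and 100 against 50 µM. A first criterion, a high recovery of 2-fold changes over all genes, was not met. A smaller dispersion with a lower bar was then tried and met that bar, and was dropped because it gave less residual variance than the real libraries. With the first dispersion restored, the criterion was reset for genes of at least 10 FPKM after those runs had been seen, so it was not fixed beforehand. With the dispersion used, the median residual variance was 0.0100 in the simulated and 0.00883 in the real libraries.

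Alternatives were other pseudocounts, filters, scalings and variance models, a block for the replicate number, voom on the rebuilt reads, and the omission of each library in turn. Removal of the authors' factor per library was added after seeing the data. Correlations between comparisons that share control libraries were set beside 100 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.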

Results

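Gene expression was measured in cultured mouse inguinal adipose cells differentiated towards white adipocytes with 0, 50 or 100 µM sodium alginate, with 3 libraries per dose. The study's title links alginate to adipocyte differentiation and the PPAR pathway, a nuclear receptor pathway of lipid metabolism. Rebuilt reads per library ranged from 14314663 to 14583502 at 0 µM, 15359348 to 16523540 at 50 µM and 14019672 to 17094467 at 100 µM. The 10 genes with the most reads took 7.75% ± 0.200 (SD, n = 3) of reads at 0 µM, 7.34% ± 0.145 at 50 µM and 8.63% ± 0.0399 at 100 µM. Within each dose the libraries differed by more than counting noise (chi-square per gene 3.26 to 7.22), so no library was counted as a second deposit of another. Whether separate preparations of 1 RNA would also differ by that much was not measured. The first principal component held 35.9% of the variance and ran from -15.0 to -10.9 for the 0 µM libraries, -9.63 to -4.30 for the 50 µM libraries and 18.2 to 21.4 for the 100 µM libraries. On the second component, with 11.9%, 50 µM library 3 stood apart at -19.1, while the other libraries lay between -4.62 and 11.4. The pairs of that library with the other 50 µM libraries had the highest chi-square per gene, 6.83 and 7.22 against 3.47 for the remaining pair, and 3.12% of its reads lay in ribosomal protein genes, against 2.69% and 2.61%.

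The first comparison asked how cells given 100 µM alginate differed from cells given none. Genes of lipid synthesis and mitochondrial metabolism rose, and matrix, inflammatory and progenitor genes fell. Thrsp, a gene tied to lipogenesis, rose from 111 ± 8.45 to 332 ± 11.7 FPKM (SD, n = 3), a log2 fold change of 1.58 ± 0.058 (SE, limma adjusted p = 5.92e-06). Adipoq, which encodes the adipocyte hormone adiponectin, rose from 594 ± 26.7 to 956 ± 64.9 FPKM. Cxcl14, a chemokine gene, fell from 30.2 ± 1.55 to 9.13 ± 0.932 FPKM, a log2 fold change of -1.63 ± 0.105 (limma adjusted p = 1.55e-05). Pdgfra, a receptor gene of adipose progenitors, fell from 52.1 ± 1.92 to 32.3 ± 1.15 FPKM. In all, 2314 genes were higher and 1965 lower at 100 µM, of 12635 tested with limma. That split depends on scaling. It was 1620 higher and 2636 lower when values were rescaled to a common sum (TPM), and 1731 higher and 2658 lower with the authors' factor per library removed, an alternative chosen after seeing the data.

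Thrsp (MGP_C57BL6NJ_G0033007) lies on chromosome 7 at 103999940 to 104004734, on the minus strand of the C57BL/6NJ assembly. Adipoq (MGP_C57BL6NJ_G0023096) lies on chromosome 16 at 21203019 to 21215045, plus strand. Cxcl14 (MGP_C57BL6NJ_G0021000) lies on chromosome 13 at 57525211 to 57533115, minus strand, and Pdgfra (MGP_C57BL6NJ_G0030068) on chromosome 5 at 78303537 to 78349133, plus strand. All are annotated as protein-coding, and values are per gene, over the exons counted by the authors.

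Among protein-coding genes past the threshold with at least 5 FPKM in the higher group and no overlap between the libraries, the 10 largest increases at 100 µM also held Slc2a4, the insulin-responsive glucose transporter (22.7 ± 2.84 to 50.9 ± 1.63 FPKM), and Cox7a1, a cytochrome oxidase subunit (39.7 ± 2.09 to 90.7 ± 9.20 FPKM). Elovl3, a fatty acid elongase, rose from 108 ± 10.7 to 239 ± 7.58 FPKM. Plin5, a lipid droplet protein, rose from 5.28 ± 0.575 to 12.8 ± 0.858 FPKM. Log2 fold changes were 1.17 for Ppp1r1a, 1.14 for Ehhadh, 1.13 for Acacb and 1.05 for Acss2. Ndufa12 also rose, by a log2 fold change of 1.22 ± 0.294, with a wide spread between control libraries (41.2 ± 22.2 FPKM) and adjusted p = 0.0111 with limma. Among the 10 largest decreases were Cxcl5, a chemokine (43.3 ± 2.28 to 15.9 ± 1.62 FPKM), and Mmp3, a matrix metalloproteinase (89.2 ± 2.05 to 39.6 ± 3.86 FPKM). Lox, which cross-links collagen, fell from 391 ± 18.3 to 197 ± 10.2 FPKM. The others were Ndufa4l2 (log2 fold change -1.29), Pdpn (-1.19), P4ha3 (-1.06), Spp1 (-1.02), Col12a1 (-0.98) and S100a6, which fell from 319 ± 32.2 to 159 ± 19.7 FPKM.

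Adipocyte and lipid lists rose at 100 µM. With the preset correlation 20 lists were called, but another split of the same libraries called 19. Every other split mixes the doses unevenly and so still holds part of the dose difference. A list call by itself thus does little to single out the real doses, but the splits do not measure calls without a dose effect. Of 27 tested markers of mature white adipocytes, 26 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.63. Agpat2, which acylates lysophosphatidic acid, rose by a log2 fold change of 0.93, and Lipe, the hormone-sensitive lipase gene, from 126 ± 4.13 to 209 ± 8.96 FPKM. In fatty acid synthesis 18 of 20 genes rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.71. Me1, which supplies NADPH, rose from 168 ± 8.60 to 328 ± 11.2 FPKM, and Fasn, the fatty acid synthase gene, from 308 ± 35.3 to 604 ± 43.9 FPKM. In triglyceride synthesis and lipid droplet genes 19 of 21 rose and 1, Hilpda, fell. In lipolysis 15 of 17 rose and 0 fell, again with the same counts adjusted over the list alone for both lists, including Ces1d (56.9 ± 4.32 to 117 ± 0.194 FPKM), which has close copies in the genome. The adjusted p of these 4 lists with camera and an estimated correlation was 0.0233 for adipocyte markers, 0.0279 for fatty acid synthesis, 0.0279 for triglyceride synthesis and 0.0233 for lipolysis.

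In PPAR signalling 34 of 44 tested genes rose and 3 fell, with the same counts adjusted over the list alone and an adjusted p of 0.0361 with an estimated correlation. The treatment protocol lists rosiglitazone in the medium at every dose, 0 µM included. Pparg, the adipogenic receptor, rose from 41.2 ± 0.749 to 54.7 ± 3.73 FPKM (log2 fold change 0.40 ± 0.0556, limma adjusted p = 0.000611). Plin1, a lipid droplet coat gene, rose from 209 ± 0.247 to 310 ± 6.70 FPKM and Slc27a1, a fatty acid transporter, from 37.5 ± 1.85 to 68.9 ± 3.47 FPKM. Log2 fold changes were 0.48 for Fabp4, 0.44 for Cd36 and 0.39 for Lpl, all past the threshold, though the Fabp4 change was 0 with quantile normalization. That normalization sets values by rank within each library, so a gene that keeps its rank shows no change whatever its level. The members that fell were Mmp3, Olr1 and Cpt1a (log2 fold changes -1.15, -0.29 and -0.16), and 5 fell on the TPM scale or with the authors' factor removed. Of 17 adipogenic transcription factors 9 rose and 0 fell, with the same counts adjusted over the list alone, and the list's adjusted p was 0.0785 with an estimated correlation. Cebpa rose from 242 ± 8.26 to 374 ± 36.3 FPKM and Srebf1 from 71.4 ± 2.06 to 109 ± 3.84 FPKM. Cebpb had 106 ± 4.69 FPKM at 0 µM and 121 ± 39.0 FPKM at 100 µM and did not pass (adjusted p = 0.580 with limma).

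Mitochondrial lists rose at 100 µM. All 61 tested genes of oxidative phosphorylation rose, over all genes and adjusted over the list alone, with a median log2 fold change of 0.58 and an adjusted p of 0.0423 with an estimated correlation. Uqcrc1, a complex III core gene, rose from 76.4 ± 0.781 to 117 ± 2.03 FPKM and Atp5b, an ATP synthase gene, from 454 ± 5.48 to 694 ± 16.1 FPKM. In fatty acid oxidation 20 of 22 genes rose and 1, Cpt1a, fell, with the same counts adjusted over the list alone and an adjusted p of 0.0233 with an estimated correlation. Hadhb, of the trifunctional protein, rose from 58.3 ± 1.86 to 96.6 ± 1.47 FPKM. Of 17 tested thermogenic and beige genes 12 rose and 1, Slc6a8, fell (3 on the TPM scale or with the authors' factor removed and 2 with median-ratio scaling). Adjusted over the list alone 12 rose and 3 fell (with Tbx1 and Alpl), and the list's adjusted p was 0.0557 with an estimated correlation. Ucp1, the uncoupling protein gene, lay under the filter at 0.192 ± 0.0208, 0.176 ± 0.0272 and 0.269 ± 0.0146 FPKM at 0, 50 and 100 µM and was not tested. Lep and Dlk1 also lay under the filter. Lep was listed at 0 in every library at 0 and 50 µM, and Dlk1 had 0.423 ± 0.0522, 0.613 ± 0.117 and 0.524 ± 0.0554 FPKM at the 3 doses.

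In cholesterol synthesis 12 of 23 genes rose and 0 fell, with 14 higher adjusted over the list alone, a median log2 fold change of 0.22 and an adjusted p of 0.0423 with an estimated correlation. Cyp51 rose from 94.3 ± 4.04 to 188 ± 15.6 FPKM. In insulin signalling and glucose uptake 14 of 24 genes rose and 3 fell (Slc2a1, Igf1r and Grb10), with 16 higher and 3 lower adjusted over the list alone. The call of that list was lost with an estimated correlation, at adjusted p = 0.223. In glycolysis and hypoxia 6 genes rose and 9 fell of 20, and the list was not called with camera (adjusted p = 0.263) but was called lower with fry (adjusted p = 0.00622), over a range of 0.00622 to 0.534 for all alternatives. Aldoa rose from 648 ± 11.3 to 921 ± 29.8 FPKM, and P4ha2 fell from 28.2 ± 0.389 to 16.5 ± 1.85 FPKM. The unfolded protein list had 7 higher and 8 lower of 32, with a median of -0.02, a mean of 0.02, a camera test towards lower values and adjusted p = 0.889. With fry it was called higher at adjusted p = 0.0437, and all alternatives ranged from 0.0437 to 0.966. The oxidative stress list had 4 higher (Sod1, Cat, Gpx4 and Srxn1) and 10 lower of 26 and adjusted p = 0.222 with camera. With quantile normalization the unfolded protein counts were 7 higher and 13 lower, and on the TPM scale 6 and 11. Adjusted over the list alone, the counts higher and lower were 8 and 9 for glycolysis, 7 and 8 for the unfolded protein list, and 5 (with Gsta3) and 10 for oxidative stress.

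**Figure D1:**
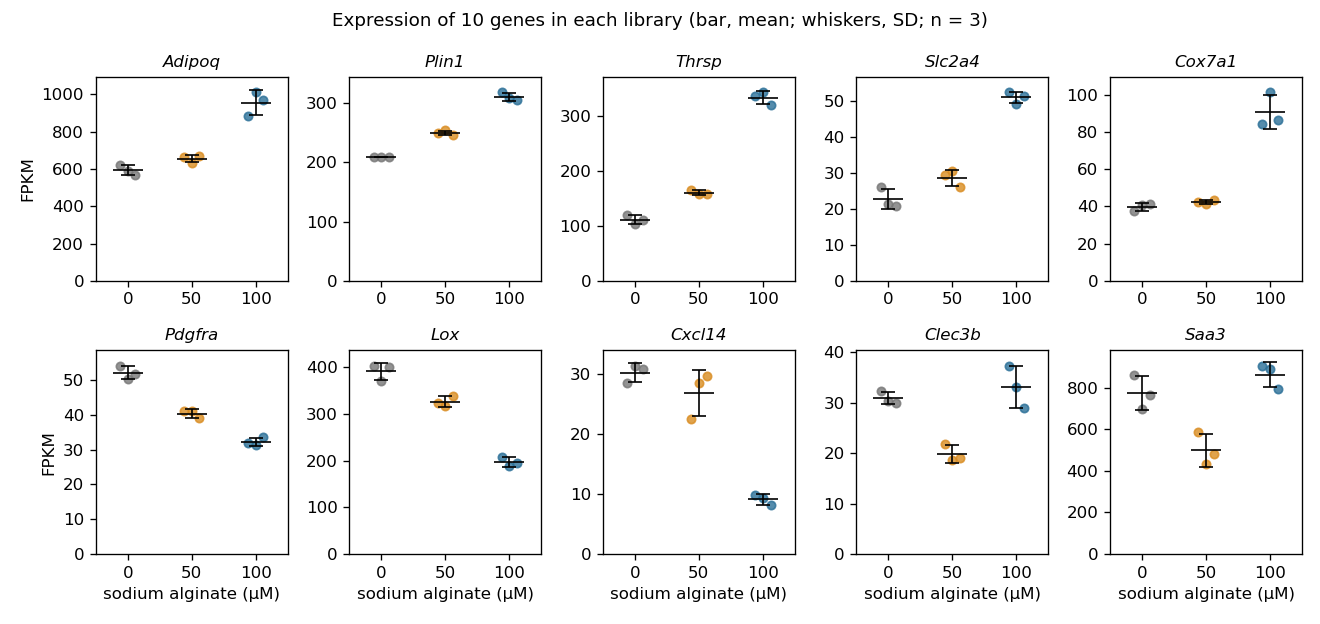
FPKM of 10 genes at 0, 50 and 100 µM sodium alginate; points are libraries, the bar is the mean and whiskers are the SD (n = 3). Adipoq, Plin1, Thrsp, Slc2a4 and Cox7a1 are highest at 100 µM, Pdgfra, Lox and Cxcl14 are lowest there, and Clec3b and Saa3 are lowest at 50 µM.

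Matrix, progenitor and signalling lists fell at 100 µM. In extracellular matrix 32 of 42 genes fell and 1, Col15a1, rose, with 35 lower and 2 higher (Col15a1 and Lum) adjusted over the list alone. The log2 fold change of Col15a1 was 0.11, and -0.02 with quantile normalization, and 0 matrix genes rose under the other 4 scalings. Loxl2 fell from 54.2 ± 1.55 to 32.8 ± 0.808 FPKM and Timp2 from 142 ± 3.24 to 93.0 ± 3.39 FPKM. Of 19 preadipocyte and stromal progenitor markers 13 fell and 0 rose, with 14 lower adjusted over the list alone and a median log2 fold change of -0.43. Anxa3 fell from 21.7 ± 2.09 to 10.7 ± 0.296 FPKM. In Wnt and TGF-beta response 17 of 26 genes fell and 0 rose, with 19 lower adjusted over the list alone. Wisp2 fell from 121 ± 5.36 to 69.1 ± 2.84 FPKM. In the inflammatory list 16 of 29 genes fell and 0 rose, with 18 lower adjusted over the list alone, including Csf1 (136 ± 5.39 to 87.1 ± 3.48 FPKM). Adjusted p with an estimated correlation was 0.0233 for matrix, 0.0361 for progenitor markers, 0.00925 for Wnt and TGF-beta and 0.0361 for inflammation.

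In cell cycle 26 of 38 genes fell and 0 rose, with 31 lower and 1 higher (Ccne1) adjusted over the list alone. Top2a fell from 13.8 ± 0.259 to 9.65 ± 0.451 FPKM, and the list's adjusted p was 0.0857 with an estimated correlation. The interferon list was called lower at adjusted p = 0.0487, with 3 genes higher (Ifi27 and Ifi27l2a among them) and 3 lower (Ddx58, Tap1 and Ifit2; 5 on the TPM scale or with the authors' factor removed) of 28, the same counts adjusted over the list alone. That call was lost at adjusted p = 0.647 with an estimated correlation, 0.393 with fry, 0.0603 with median-ratio scaling and 0.156 with the authors' factor removed. It was also lost without control library 3, 50 µM library 1 or 100 µM library 2, at adjusted p = 0.419, 0.0561 and 0.252, and over all alternatives its adjusted p ranged from 0.00379 to 0.647.

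Markers of other cell types moved in the same libraries as the adipocyte, progenitor and matrix lists. Of 20 macrophage and myeloid markers 13 fell and 0 rose, with a median log2 fold change of -0.31. Of 18 endothelial markers 16 fell and 0 rose, with a median of -0.33. Adjusted over the list alone these counts were the same. Of 16 smooth muscle and pericyte markers 8 fell and 2 rose (Cspg4 and Mcam; 1 with quantile normalization, on the TPM scale or with the authors' factor removed), with a median of -0.31, and 9 fell and 2 rose adjusted over the list alone. Fcgr3 fell from 20.3 ± 1.90 to 14.2 ± 0.280 FPKM, Pecam1 from 31.0 ± 1.49 to 24.8 ± 0.673 FPKM and Acta2 from 177 ± 16.1 to 114 ± 7.12 FPKM. Adjusted p with an estimated correlation was 0.0233 for macrophage, 0.0655 for endothelial and 0.0361 for smooth muscle markers. For each of the 20 lists called at 100 µM this was the highest adjusted p over 15 alternatives, the lowest lying between 1.40e-32 for oxidative phosphorylation and 0.00379 for the interferon list. Krt19 and Gpm6a fell among 4 tested mesothelial markers and Ngfr among 3 Schwann markers. Neither of 2 tested skeletal muscle genes passed over all genes, 1 (Mylpf) was lower adjusted over the list alone, and 0 epithelial, lymphocyte or erythroid markers were above the filter.

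**Figure D2:**
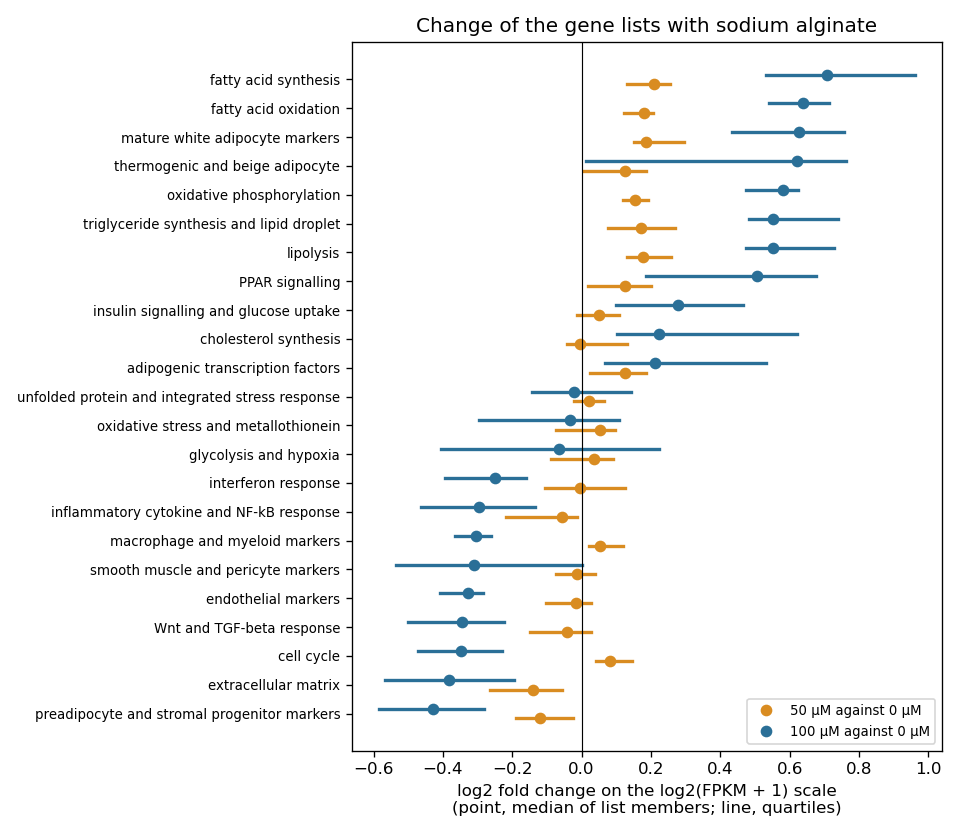
Median log2 fold change of each tested gene list, on the log2(FPKM + 1) scale, for 50 µM and 100 µM against 0 µM; lines run between the quartiles of the list's genes. Fatty acid synthesis has the highest median at 100 µM (0.71) and progenitor markers the lowest (-0.43).

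The next comparison asked how cells given 50 µM alginate differed from the same controls. A small set of adipocyte and lipid genes rose and a few progenitor and matrix genes fell. Thrsp rose from 111 ± 8.45 to 160 ± 4.51 FPKM (SD, n = 3), a log2 fold change of 0.53 ± 0.058 (SE, limma adjusted p = 0.0253). Plin1 rose from 209 ± 0.247 to 250 ± 3.81 FPKM and Pdgfra fell by 0.36 ± 0.0448 on the log2 scale. Saa3, an acute-phase gene, fell from 773 ± 80.4 to 499 ± 79.1 FPKM (log2 fold change -0.64 ± 0.116, limma adjusted p = 0.0481). In all, 45 genes were higher and 55 lower of 12635 tested with limma, against 1814 genes at an unadjusted p below 0.05. With quantile normalization the split was 33 higher and 74 lower.

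Without control library 1, control library 2 or 50 µM library 2, limma called 0 genes at 50 µM, against 1493, 1547 and 1636 at an unadjusted p below 0.05, while without control library 3 it called 1 (Mir7646) and without 50 µM library 1, 50 µM library 3 or 100 µM library 2 it called 42, 13 and 53. With only the 2 groups in the fit limma called 0 genes (1837 at an unadjusted p below 0.05), with no filter on low values 12, and with voom on the rebuilt reads of all 9 libraries 348.

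By the same rule, which leaves out the larger change of Orm1 (0.899 ± 0.293 to 3.08 ± 0.646 FPKM), the largest increases at 50 µM besides Thrsp were Elovl3 (108 ± 10.7 to 150 ± 3.52 FPKM), Plbd1 (log2 fold change 0.44), A530016L24Rik (0.43), Car2 (0.41), Pfkfb1 (0.39), Nat8l (0.39), Tmem45b (0.38), Me1 (0.37) and Tspo (0.37). The largest decreases besides Saa3 were Clec3b (30.9 ± 1.24 to 19.8 ± 1.70 FPKM), Cpxm1 (log2 fold change -0.59), Fam46c (-0.54), Col28a1 (-0.50), C7 (-0.49), Pdpn (-0.47), Ngfr (-0.45), Susd2 (-0.45) and Slc7a8 (-0.44). Of the genes always reported, Pparg had 41.2 ± 0.749 FPKM at 0 µM and 46.2 ± 2.08 FPKM at 50 µM (limma adjusted p = 0.222). Adipoq, Cebpa, Cebpb, Cd36, Fabp4, Lpl and Fasn did not pass at 50 µM, with log2 fold changes of 0.14, 0.25, 0.24, 0.17, 0.10, 0.06 and 0.26. Cebpa and Cd36 did pass under some alternatives, over limma adjusted p ranges of 0.0210 to 0.296 and 0.0344 to 0.540.

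By list, few genes passed at 50 µM over all genes and more passed adjusted over the list alone. With the preset correlation 14 lists were called, while another split of the same libraries called 18, so a call by itself does not single out this dose. That split also mixed the doses unevenly and held part of any dose difference, so it does not measure calls without one. Of 27 adipocyte markers 5 rose (Plin1, Lipe, Cidec, Agpat2 and Orm1), and 15 adjusted over the list alone. Lipe rose from 126 ± 4.13 to 158 ± 3.14 FPKM. Of 20 fatty acid synthesis genes 5 rose (Thrsp, Me1, Taldo1, Tkt and Acss2), and 13 adjusted over the list alone. Triglyceride genes had 3 of 21 higher (Plin1, Cidec and Agpat2), and 13 adjusted over the list alone, lipolysis 3 of 17 (Plin1, Lipe and Prkaca), and 10 adjusted over the list alone, and fatty acid oxidation 2 of 22 (Acads and Eci1), and 17 adjusted over the list alone. In extracellular matrix 4 of 42 genes fell (Postn, Mmp2, Mmp14 and Fmod), and 20 adjusted over the list alone. In Wnt and TGF-beta response 1 of 26 fell (Tgfbr2), and 3 adjusted over the list alone (with Sfrp1 and Sfrp2). These 7 lists were called, each at adjusted p = 0.0476 with an estimated correlation, and some share genes, such as Plin1, Lipe, Cidec and Agpat2. Their counts over all genes depended on scaling. With quantile normalization 2 fatty acid synthesis, 1 triglyceride and 1 lipolysis gene were higher, on the TPM scale 3 fatty acid synthesis genes were, and with the authors' factor removed 4 fatty acid oxidation genes were.

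Another 7 lists were called at 50 µM with the preset correlation and lost the call with an estimated one. PPAR signalling had 2 of 44 genes higher (Plin1 and Me1; 1 with quantile normalization), 12 adjusted over the list alone, and adjusted p = 0.106 with an estimated correlation. Oxidative phosphorylation had 1 of 61 higher (Uqcrc1; 2 with quantile normalization and 0 on the TPM scale), 32 adjusted over the list alone, and adjusted p = 0.116 with an estimated correlation. Adipogenic transcription factors had 0 of 17 past the threshold with limma (6 higher and 1 lower at an unadjusted p below 0.05) and 3 higher adjusted over the list alone (Cebpa, Srebf1 and Nr1h3), with adjusted p = 0.230 with an estimated correlation and 0.0658 without 50 µM library 2. Thermogenic genes had 1 of 17 higher on either count (Elovl3), with adjusted p = 0.160 with an estimated correlation and 0.0751 without 50 µM library 1. Progenitor markers had 2 of 19 lower (F3 and Pdgfra), 4 adjusted over the list alone (with Meox2 and Cd34), and adjusted p = 0.129 with an estimated correlation. The inflammatory list had 1 of 29 lower (Saa3; 3 with quantile normalization or the authors' factor removed and 2 with median-ratio scaling), 7 adjusted over the list alone, and adjusted p = 0.0735 with an estimated correlation. Cell cycle had 0 of 38 past the threshold on either count with limma (5 higher at an unadjusted p below 0.05), a median of 0.08, and adjusted p = 0.379 with an estimated correlation, 0.153 with fry and 0.0640 without 50 µM library 3. For each of the 14 lists called at 50 µM the value with an estimated correlation was the highest over 15 alternatives, the lowest lying between 8.76e-24 for oxidative phosphorylation and 0.000974 for thermogenic genes. Macrophage, endothelial and smooth muscle markers were not called at 50 µM and held 0 genes past the threshold with limma (3 higher, 3 lower and 1 higher at an unadjusted p below 0.05), with medians of 0.05, -0.02 and -0.01. Endothelial markers were called lower without control library 1 (adjusted p = 0.00199) or 50 µM library 3 (adjusted p = 0.00230), over a range of 0.00199 to 0.534 for all alternatives. Cholesterol, insulin, glycolysis, interferon, unfolded protein and oxidative stress lists were not called with camera either. With fry the unfolded protein list was called higher (adjusted p = 0.0335, over a range of 0.0335 to 0.447 for all alternatives), though its median of 0.02 was -0.007 with quantile normalization. Among them Adm and Gpx3 fell over all genes. Adjusted over the list alone, 5 cholesterol genes were higher (Insig1, Cyp51, Sc5d, Dhcr7 and Nsdhl) and 1 lower (Idi1). On that count there were also 1 glycolysis gene higher (Aldoa) and 2 lower (Adm and P4ha1), 4 unfolded protein genes higher (Dnajb9, Psat1, Mthfd2 and Ppp1r15a), and 1 oxidative stress gene higher (Srxn1) and 1 lower (Gpx3). The cholesterol list had a median of -0.004, a mean of 0.03 and a test towards higher values, and the interferon list a median of -0.004, a mean of 0.02 and a test towards lower values. Insulin signalling was called higher without control library 1 (adjusted p = 0.0107) or 50 µM library 3 (adjusted p = 0.00313), and interferon without control library 3 (adjusted p = 0.00496), over ranges of 0.00313 to 0.660 and 0.00496 to 0.986. Ngfr fell among 3 Schwann markers, and 0 of 4 mesothelial and 2 muscle genes passed.

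The comparison of 100 µM with 50 µM asked how the higher dose differed from the lower. Lipid and mitochondrial genes were higher and matrix, cell cycle and progenitor genes lower. Plin5 was higher at 100 µM, at 12.8 ± 0.858 against 5.41 ± 0.517 FPKM (SD, n = 3; log2 fold change 1.11 ± 0.0853, limma adjusted p = 0.000194). Cox7a1 had 90.7 ± 9.20 against 42.2 ± 0.988 FPKM and Ppara, a receptor gene of fatty acid oxidation, 14.8 ± 1.38 against 6.85 ± 1.31 FPKM. Cxcl14 was lower, at 9.13 ± 0.932 against 26.8 ± 3.87 FPKM, and Ctgf, a matrix-associated growth factor gene, at 40.1 ± 0.982 against 89.1 ± 12.1 FPKM. In all, 1663 genes were higher and 1510 lower at 100 µM than at 50 µM with limma. The split was 1050 higher and 2040 lower on the TPM scale and 1102 higher and 2180 lower with the authors' factor removed.

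By that rule the other large increases from 50 to 100 µM were Thrsp (log2 fold change 1.05), Cox8b (0.98), Fmo1 (0.95), Acacb (0.87), Ppp1r1a (0.83), Slc2a4 (0.82) and Saa3 (0.80). Other large decreases included Ndufa4l2 (-1.50), Aqp1 (-1.26), Cxcl5 (-1.17), S100a6 (-1.10), Spp1 (-1.09), Mmp3 (-1.08) and Krt19 (-1.05). Adipoq (0.54), Cebpa (0.38), Pparg (0.24), Fabp4 (0.38), Cd36 (0.27), Lpl (0.33), Plin1 (0.31) and Fasn (0.71) were higher and Pdgfra (-0.31) lower. The Fabp4 log2 fold change turned to -0.06 under quantile normalization. Fabp4, Cd36 and Lpl lost their calls with no filter on low values (adjusted p = 0.208, 0.0751 and 0.0703, the last 2 the highest over all alternatives, with 7.79e-05 and 4.81e-06 as the lowest), and Fabp4 also with quantile normalization (adjusted p = 0.555, over a range of 2.05e-05 to 0.555). Pparg lost its call with quantile normalization (adjusted p = 0.0593) and on the TPM scale (adjusted p = 0.0875), over a range of 0.00290 to 0.0875 for all alternatives. Cebpb did not pass (-0.09, limma adjusted p = 0.748), and without 100 µM library 1 it was lower at adjusted p = 0.0311, over a range of 0.0311 to 0.981 for all alternatives.

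Between 50 and 100 µM, 23 of 27 adipocyte markers, 18 of 20 fatty acid synthesis genes and 20 of 22 fatty acid oxidation genes were higher, with the same counts adjusted over the list alone, and 1 fatty acid oxidation gene, Cpt1a, was lower. In oxidative phosphorylation 55 of 61 were higher, 58 adjusted over the list alone, in cholesterol synthesis 15 of 23, 17 adjusted over the list alone, in lipolysis 15 of 17, 16 adjusted over the list alone, and in triglyceride genes 18 of 21, 19 adjusted over the list alone, with 1, Hilpda, lower. In PPAR signalling 31 of 44 were higher and 4 lower (Mmp3, Olr1, Acsl4 and Cpt1a), with 32 higher and 4 lower adjusted over the list alone. Cell cycle had 29 of 38 genes lower, 30 adjusted over the list alone, with Ccnd1, the cyclin D1 gene, at 9.76 ± 0.644 against 19.2 ± 2.90 FPKM. Macrophage markers had 15 of 20 lower, 17 adjusted over the list alone, with C1qc at 16.0 ± 0.332 against 22.9 ± 1.65 FPKM. Progenitor markers had 10 of 19 lower, with 11 lower and 1 higher (Fap) adjusted over the list alone. Matrix genes had 19 of 42 lower, 20 adjusted over the list alone, and 2 higher on either count (Mmp2 and Lum; 1 under each other scaling). Wnt and TGF-beta genes had 13 of 26 lower, 17 adjusted over the list alone, and smooth muscle markers 8 of 16 lower on either count, with 1 higher (Cspg4) adjusted over the list alone. These lists kept their call with an estimated correlation, at adjusted p from 0.0112 for Wnt and TGF-beta to 0.0479 for oxidative phosphorylation, progenitor markers and cell cycle. With the preset correlation, another split of the same libraries called as many lists as the real doses, 20. That split mixed the doses unevenly and so still held part of the dose difference.

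The remaining lists called between 50 and 100 µM lost their call with an estimated correlation. Adipogenic transcription factors (6 of 17 higher, 9 adjusted over the list alone) had adjusted p = 0.0971 with an estimated correlation. Thermogenic genes (9 of 17 higher, 11 adjusted over the list alone, and 2 lower on either count, Slc6a8 and Alpl) had adjusted p = 0.0663 with an estimated correlation. Insulin signalling (14 of 24 higher, 15 adjusted over the list alone, and 3 lower on either count, Grb10, Slc2a1 and Igf1r) had adjusted p = 0.209 with an estimated correlation, and on the TPM scale 8 genes higher. The inflammatory list had 13 of 29 genes lower, 18 adjusted over the list alone, and 5 higher on either count (Saa3, C3, Hp, Cxcl12 and Tnfaip3; 3 with quantile normalization, on the TPM scale or with the authors' factor removed), with adjusted p = 0.0813 with an estimated correlation. Endothelial markers (14 of 18 lower, 15 adjusted over the list alone) had adjusted p = 0.0729 with an estimated correlation. The interferon list had 1 of 28 genes lower on either count (Tap1) and 3 higher (Ifi27 and Ifi27l2a among them), 2 of them (Ifi27 being 1) adjusted over the list alone. On the TPM scale or with the authors' factor removed 3 were lower and 1 higher. The list had adjusted p = 0.588 with an estimated correlation, 0.334 with fry and 0.117 with the authors' factor removed, and 0.0793, 0.145 and 0.223 without 50 µM library 1, 50 µM library 3 or 100 µM library 2. For each of the 20 called lists the value with an estimated correlation was the highest over 15 alternatives, the lowest lying between 7.95e-32 for oxidative phosphorylation and 0.00168 for the interferon list. Glycolysis (3 of 20 higher, Aldoa, Gpi1 and Hk2, and 7 lower, and 4 higher, with Tpi1, and 9 lower adjusted over the list alone) was not called with camera (adjusted p = 0.0850) and was called lower with fry (adjusted p = 0.00484). Nor was the unfolded protein list (6 of 32 higher and 9 lower, and 7 and 9 adjusted over the list alone; adjusted p = 0.392) called with camera. Oxidative stress genes (2 of 26 higher, Sod1 and Cat, or 1 with quantile normalization, and 8 lower, and 3, with Gpx4, and 8 adjusted over the list alone) were not called (adjusted p = 0.0984). Without 50 µM library 2 the glycolysis and oxidative stress lists were called lower, at adjusted p = 0.0456 and 0.0350, and without 100 µM library 2 the latter was, at 0.0444; over all alternatives their ranges were 0.00484 to 0.317 and 0.0350 to 0.501. Krt19 and Gpm6a were lower among 4 mesothelial markers and Mylpf among 2 muscle genes, and 0 of 3 Schwann markers passed.

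**Figure D3:**
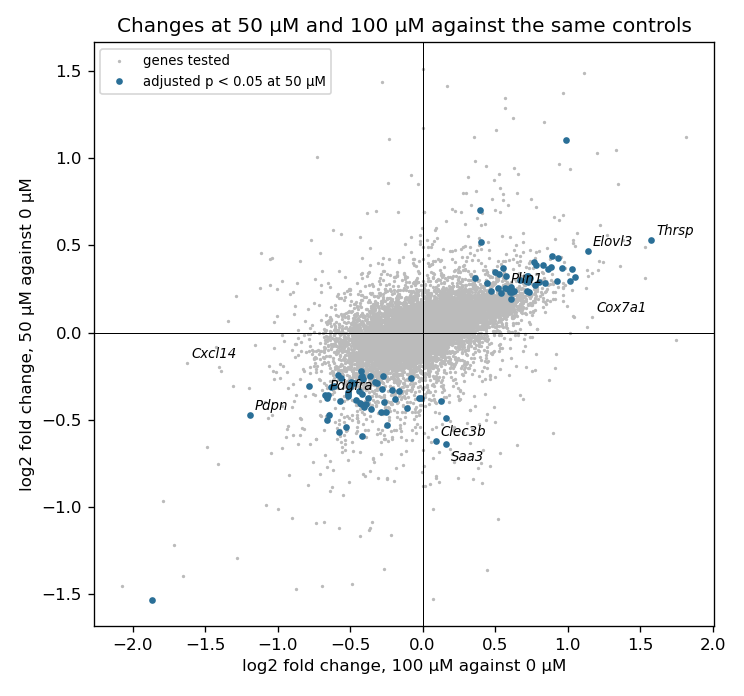
Log2 fold change at 50 µM (vertical) against that at 100 µM (horizontal), both against 0 µM and on the log2(FPKM + 1) scale, for 12635 genes; blue points are the 100 genes called at 50 µM. Thrsp and Elovl3 lie to the upper right and Pdpn to the lower left, while Saa3 and Clec3b lie at -0.64 and -0.62 on the vertical axis and 0.16 and 0.09 on the horizontal axis.

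Over the 3 doses, 3853 genes differed by the limma F test, and 2156 genes had a rising and 1649 a falling trend, as a fitted slope on dose. The slope does not test whether a change is linear. A limma test of curvature called 188 genes, 125 with the 50 µM mean above and 63 with it below the midpoint of the other doses. On the TPM scale the trend split was 1514 rising and 2275 falling, and with the authors' factor removed it was 1619 and 2223. Of the genes called at 50 µM, 45 were also called higher at 100 µM and 46 also lower, with 0 in opposite directions. Independent lists of these sizes would share 8.24 and 8.55 genes, a value that leaves out the shared controls. Simulated unchanged groups against the same controls shared 0.01 genes on average in each direction and at most 1, a value that leaves out the effects. Across genes, which are not independent replicates, the changes at 50 and 100 µM had Pearson r = 0.488 and Spearman rho = 0.530. Simulated unchanged groups sharing the same controls gave r = 0.496 and rho = 0.459 on average. The observed r lay inside the simulated range of 0.435 to 0.558 and the observed rho above that of 0.442 to 0.478. The covariance was 0.0259 against 0.00936 in the simulations, and 69.7% of genes had the same sign against 66.6%. With the simulated covariance and variance subtracted, the changes at 50 µM had a slope of 0.233 on those at 100 µM. The simulations already hold shared controls with the spread of each gene within a dose. They drew genes independently, however, whereas a real library can deviate in many genes together, so their ranges and counts may be too narrow. The 3 controls could not be split with 2 in each part, so a shift common to all controls was not checked and may give part of the excess.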

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

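The removal of the authors' factor was chosen after seeing the data, and the other alternatives were planned. For 50 µM against 0 µM the count of 100 genes became 12 with no filter on low values, 269 with a mean of at least 10 FPKM, 182 with array weights, 194 with protein-coding genes only, 348 with voom, 0 with only the 2 groups in the fit, 2 (Orm1 and Mir7227) with a log2 fold change of at least 1, and 0 to 112 without single libraries. With a block for the replicate number it was 0 (1603 at an unadjusted p below 0.05). The numbers did not pair the libraries, since same-numbered residuals correlated at -0.094 to 0.041 and 0 libraries matched best with their own number, and the block moved no other count by over 1.5 times. With a mean of at least 10 FPKM, which tests fewer genes, the counts were 2638 for 100 against 0 µM, 2104 for 100 against 50 µM, 2460 for the F test and 2464 for the trend. With a log2 fold change of at least 1 they were 43, 36 and 41 for 100 against 0 µM, 100 against 50 µM and the trend. Without single libraries, 100 against 0 µM gave 3414 to 4322 genes and 100 against 50 µM 2277 to 3033. Lists called at 50 µM fell from 14 to 7 with an estimated correlation. The correlation of the changes at 50 and 100 µM ranged from 0.404 to 0.550 without single libraries. Without single libraries the log2 fold change of Cebpb, which did not pass, ranged from -0.102 to 0.309 at 100 against 0 µM and from -0.341 to 0.0698 at 100 against 50 µM, that of Fabp4 at 100 against 50 µM was -0.0649 and that of Tpi1, past the threshold over its list alone, was -0.0484 with quantile normalization, and that of Col15a1 at 100 against 0 µM was -0.0170 with it. Except where a changed set of genes or libraries gives it, the cause was not tested. Of the genes named in the text and past the threshold, 72 of 90 kept their call wherever they were tested under the other alternatives, the bound of 1 on the log2 fold change left aside, at 100 against 0 µM, 37 of 56 at 100 against 50 µM and 0 of 42 at 50 against 0 µM. At 100 against 0 µM the calls of Col11a2, Col15a1, Col5a3, Cpt1a, Cspg4, Ddx58, Gpm6a, Gpx4, Hilpda, Mcam, Rpl22, Rps20, Rps3, Slc25a12, Slc25a45 and Srxn1 were lost without at least 1 library, that of Fabp4 with quantile normalization or no filter, and that of Rpl4 with no filter. At 100 against 50 µM the calls of Acsl4, Cox8b, Cpt1a, Cxcl12, Gpm6a, Hilpda, Hp, Ifi27l2a, Igf1r, Mmp2, Mylpf, Olr1 and Tnfaip3 were lost without at least 1 library, and those of Cat, Cd36, Fabp4, Gpi1, Lpl and Pparg with another scaling or filter. Of the genes named in the text and not past the threshold over all genes, some passed or changed sign under an alternative. At 50 against 0 µM 14 of 28 kept their result throughout. At 100 against 0 µM 0 of 7 did, and at 100 against 50 µM 0 of 5. In the simulations, fewer of the changed genes were recovered under 10 FPKM or with small changes, so a gene there that did not pass may still have changed.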

Other observations

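The tests of further gene groups, of explanations and of other splits in this part were chosen after the results they bear on had been seen, as were the bounds they were read against. Besides the lists fixed beforehand, 21 further gene groups were tested. At 100 µM against 0 µM all 18 tested genes of the tricarboxylic acid cycle and pyruvate entry rose, with a median log2 fold change of 0.64. Cs, the citrate synthase gene, rose from 334 ± 6.19 to 558 ± 24.2 FPKM (SD, n = 3) and Pcx, the pyruvate carboxylase gene, from 213 ± 12.7 to 384 ± 9.21 FPKM. In branched-chain amino acid breakdown 17 of 19 genes rose and 0 fell, with Bcat2 going from 83.8 ± 1.57 to 153 ± 3.76 FPKM. Mitochondrial ribosomal proteins rose in 65 of 73 genes, with a median of 0.35, while cytosolic ribosomal proteins had 0 higher and 5 lower (Rpl4, Rps3, Rps20, Rpl22 and Rpl5) of 73 and a median of -0.17. Peroxins, which build peroxisomes, rose in 12 of 16 genes, mitochondrial membrane translocases in 14 of 18, and mitochondrial carriers in 21 of 36, with 4 lower (Slc25a37, Slc25a24, Slc25a45 and Slc25a12). With the preset correlation all these groups were called with camera, at adjusted p from 2.97e-19 for mitochondrial to 0.000443 for cytosolic ribosomal proteins. Adjusted p with an estimated correlation was 0.0526 for the tricarboxylic acid cycle, 0.0526 for branched-chain amino acid breakdown, 0.0526 for translocases, 0.0853 for mitochondrial and 0.517 for cytosolic ribosomal proteins, 0.0338 for peroxins and 0.0259 for carriers.

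Genes of secreted products were tested too, at 100 µM against 0 µM. Of 23 metalloproteinase genes 12 fell and 1 (Mmp28) rose, with adjusted p = 2.76e-05 with the preset and 0.0338 with an estimated correlation. Adamts5 fell from 71.2 ± 0.823 to 45.0 ± 2.43 FPKM. Of 17 chemokine genes 10 fell and 0 rose, with adjusted p = 1.56e-05 with the preset and 0.144 with an estimated correlation. Ccl2 fell from 182 ± 7.94 to 131 ± 3.97 FPKM. Of 22 collagen genes 12 fell and 3 rose (Col5a3, Col15a1 and Col11a2), with adjusted p = 0.000185 with the preset and 0.328 with an estimated correlation. Proteasome subunits had 23 of 34 genes higher and 0 lower, with adjusted p = 1.43e-06 with the preset and 0.154 with an estimated correlation. Of 10 transcription factor families 1, ETS, was called lower at 100 µM against 0 µM, at adjusted p = 0.0336 with the preset and 0.144 with an estimated correlation. At 100 µM against 50 µM ETS and Fork head were called lower and THR-like higher, at adjusted p = 0.00549, 0.0321 and 0.0450 with the preset and 0.0875, 0.163 and 0.163 with an estimated correlation. At 50 µM against 0 µM zf-C2H2 was called lower, at adjusted p = 0.00912 with the preset and 0.181 with an estimated correlation. Membership of 3 groups was corrected after a first run, in which name patterns had taken in genes of other kinds.

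Adipocyte genes rose and stromal genes fell together at 100 µM, which a larger share of adipocytes in the culture could produce without a change within cells. Of 20 fatty acid synthesis genes 8 rose more than the mean of Adipoq, Plin1 and Cidec and 6 less, and with Adipoq, Plin1 or Cidec alone as the reference 7, 10 and 6 rose more and 5, 4 and 8 less. For those that rose more, that argues against a larger share of adipocytes alike in these genes as the whole cause. A bound of at least 5 fatty acid synthesis genes above the reference was met, and Thrsp rose by a further 0.92 (log2). The 54 genes in all above the reference were 2.33% of those called higher, under a bound of 5% read as going with cell share. These bounds point opposite ways. The reference is not uniform either, since 10 of 27 adipocyte markers rose less than it and 4 more. The comparison therefore does not decide the matter if the adipocytes of the culture differ in these genes. For the other genes cell share and a change within cells cannot be told apart: macrophage, endothelial, smooth muscle and progenitor medians passed in 0 of 6 differences when genes were permuted, but their intervals reached from -0.334 to 0.439. The adipocyte list median of 0.63 was 0.556 with the authors' factor removed and 0.609 with a trend on gene length removed, so neither accounts for the pattern. A higher dose of alginate acting on differentiation stays an open explanation, as do handling differences between the doses, which were not tested.

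At 50 µM against 0 µM 1 of the 6 differences passed, in that macrophage markers lay 0.172 (log2) above progenitor markers (95% interval over genes 0.0913 to 0.243, adjusted p = 0.000360 by permutation of genes, which are not replicates). Per library this difference was 0.0730 to 0.210 at 50 µM and -0.0219 to 0.0270 at 0 µM, with the lowest value at 50 µM in library 3. These values are relative to the mean of the control libraries, which keeps the control values near 0. The gap between the doses per library is thus partly built in and adds little. The difference over genes argues against a share of all other cells falling alike as the whole cause at 50 µM. The permutation takes the markers as independent, however, and the pair followed per library was the one with the lowest p. With an estimated correlation the progenitor list lost its call at 50 µM (camera adjusted p = 0.129). A lower share of progenitors alone, a change within cells and the dose itself stay open. At 100 µM the same difference was 0.124 (interval -0.0333 to 0.249, adjusted p = 0.125).

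A set of 11 genes was lower at 50 µM and higher again at 100 µM, including Saa3 (773 ± 80.4, 499 ± 79.1 and 862 ± 61.6 FPKM; SD, n = 3) and Clec3b (30.9 ± 1.24, 19.8 ± 1.70 and 33.1 ± 4.21 FPKM). Libraries were simulated with the 50 µM mean on the line between the fitted means at 0 and 100 µM. Dose-ordered changes of another shape were not simulated. The simulated libraries gave at most 1 such gene, and at an unadjusted p below 0.05 at most 66 genes lower and then higher and 66 higher and then lower, against 116 and 122 observed (without 50 µM library 1, 2 or 3 the former was 151, 113 and 134 and the latter 199, 117 and 71, the last near the bound). All 11 passed a limma test of curvature (adjusted p 0.0245 to 0.0444), which a dose-ordered change that bends would also pass, whereas 0 of the 11 passed the stricter test of both changes at once, with 0.195 as the lowest adjusted p. The count was 0 without control library 1, 2 or 3 or without 50 µM library 2. It was 13 and 3 without 50 µM library 1 or 3, and 9, 5 and 5 without 100 µM library 1, 2 or 3. Without control library 1 or 2 or 50 µM library 2, limma called 0 genes at 50 µM against 0 µM, so no such gene could be counted. Without any 1 of the 50 µM libraries all 11 kept both signs. Their median curvature of -0.38 was 113%, 95.5% and 98.7% of its size without library 1, 2 and 3. For each gene the curvatures without library 1, 2 and 3 average to the full one. Sizes near 100% therefore do not show that the dip is free of spread between libraries. These 11 genes were chosen for the dip, and the bounds come from simulation, so spread between libraries around a dose-ordered change cannot be told apart from a dip at 50 µM.

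Other splits of the same libraries were counted for each result. For the F test and the trend, the other splits were drawn at random from all regroupings. For the F test, 1 of 100 splits, the real one, gave as many as 3853 genes, so a random assignment of these libraries was excluded at 0.05. A difference between cultures was not, since the labels do not say whether the libraries of a dose came from separate cultures. The highest others gave 3209, 3160 and 2925, and these kept the 3 libraries of 100 µM together, a structure that the 100 µM group sets. For the trend, 1 of 100 splits, the real one, reached 3805 genes and the highest other drawn gave 2. A random assignment of the libraries was thus excluded there too, though splits that were not drawn could give more. Between 2 doses there are 10 splits, too few for a share under 0.05. The real counts were 100, 4279 and 3173 genes for 50 against 0, 100 against 0 and 100 against 50 µM, and the highest other gave 1 for each, so that 1 of 10 splits, the real one, gave as many. Gene lists called numbered 14 at 50 against 0 µM, where the highest other gave 18 and 2 of 10 splits gave as many. They numbered 20 at 100 against 0 µM, where the highest other gave 19, and 20 at 100 against 50 µM, where another split also gave 20. The number of lists called with the preset correlation thus does little to set the real doses apart from other splits. The other splits between 2 doses mix them unevenly, however, and so still hold part of the dose difference. They do not measure how many lists would be called without it.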
